A study of Oryza sativa with 6 samples.

How the data were processed

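RNA sequencing was analysed for 6 samples of rice (Oryza sativa): 3 of wild-type Nipponbare and 3 of the knockout line pine1-1a. Each sample pooled 8 plants, cut to about 1 cm at the base, 20 days after germination in 16 h days. Groups and replicate numbers came from the sample titles. Per the labels' protocols, messenger RNA was enriched with oligo(dT) beads, fragmented and copied with random hexamers. Whether the libraries keep strand is not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart.

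Per the submitters' processing notes, FastQC, STAR, HTSeq and DESeq2 were used with the genome build IRGSP-1.0; versions and settings are not given in the sources used here. The deposited sheet stacks 2 tables. The upper one, headed as normalized reads, holds a signal per gene and library for 27397 genes, which the authors made by dividing gene counts by 1 size factor per library. This was read from the values: 100% of them in every library are whole multiples of 1 step, within 0.001 reads, so the whole reads could be recovered. The smallest sum of recovered reads over the 6 libraries is 10, so genes with fewer reads are not analysed here. The lower table is the authors' own DESeq2 comparison of 1962 genes, with a log2 fold change, its standard error on the log2 scale, a p-value and an adjusted p-value, per the file headers. Its signs match wild type over pine1 in all 1961 genes found in both tables of the authors. Gene names and descriptions were taken from the authors' deposited table alone, where 805 genes have a symbol, so genes outside it carry a locus identifier only. The RefSeq gene table at hand, of another assembly (ASM3414082v1), matched 1 identifier and gave no names, and genome coordinates are not used here. The chromosome of a gene is the one in its locus identifier.

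The design fixed before the data were examined assumed raw counts and named edgeR's quasi-likelihood test, with limma in its place for normalized values. Because the deposited values are normalized, limma was used: log2(normalized reads + 1) was fitted by genotype with empirical Bayes moderation and an intensity trend, and p-values were adjusted by Benjamini-Hochberg over the genes tested. For the same reason the gene list test ran on this scale instead of log2 CPM. Fold changes are on the log2(value + 1) scale, which understates those of genes with no or almost no reads in a genotype and depends on the added 1 in genes with few reads. Genes were kept by edgeR's filterByExpr on the recovered reads with a minimum count of 10, which left 24149. A gene is called at an adjusted p under 0.05. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

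Named genes were chosen by a rule fixed beforehand. It takes PINE1; then, among called genes with separate groups, a mean of at least 5 CPM (recovered reads scaled to equal library totals) in the higher group and an informative name, the 8 with the largest rise and the 8 with the largest fall; then up to 2 called members per direction of each gene list; and any member of the flowering and gibberellin lists. The second part had 899 genes to choose from. Genes named outside the rule are said to be chosen after their values were seen.

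The 34 gene lists were also fixed beforehand, as loci written from memory, as patterns on gene names, or both. Of 78 distinct loci, 68 are in the normalized table, and all 13 that the authors' deposited table names carry a name that fits. Lists with at least 5 fixed loci tested, 7 in all, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 7 lists. Name patterns could match only genes in the authors' deposited table, which were chosen by a test on these same libraries. Counts from name matches are therefore counts of called genes, with no enrichment, and are not independent evidence of direction. For the 11 lists with at least 5 called members, the split into higher and lower was compared with that of the other named called genes by a two-sided Fisher's exact test. It was added after the data were examined, and adjusted over the 11 lists. This test treats each called gene as an independent draw. Members of a list can vary together across the same libraries, so its p-values can be too small. Name patterns also matched some genes that do not do what the list says, and these are named where they weigh on a count.

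Recovered reads per library ranged from 27918842 to 36250239. Where every library of a genotype had 0 reads, a fold is given as a lower bound against a floor of 3 reads per library. Where a genotype had 1 to 4 reads in all its libraries together, the ratio of reads is given with an exact 95% interval. Bounds and intervals cover counting error only, since reads carried no molecular identifiers. Members of near-identical families (histones, chlorophyll-binding proteins, aquaporins, laccases, F-box genes, transposons) may share reads, and their values are uncertain to that extent.

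Alternatives fixed beforehand were other scalings (median of ratios, upper quartile), DESeq2 and limma-voom on the recovered reads, no filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, a test against a fold of 1.5, pseudocounts of 0.1 and 5, leaving out each library in turn, and camera with an estimated correlation or fry for the lists. Added after the data were examined were edgeR's quasi-likelihood test on the recovered reads, TMM scaling, and further settings for PINE1 and the named genes. On the recovered reads edgeR called 979 genes higher and 589 lower in pine1.

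The gene test was tested on simulated counts for the 24149 genes, with 200 genes changed, all with a mean above 20 normalized reads. It recovered 51.5% of genes changed 1.5-fold, 78.8% of those changed 2-fold and 100% of those changed 4-fold, and 20 of its 173 calls were unchanged genes. In 6 further draws it recovered 50.0% to 66.2%, 80.3% to 90.9% and 93.9% to 98.5% of these, and between 4 of 159 and 22 of 185 calls were unchanged genes, so the share of false calls was above the nominal one in most draws. In the simulated lists, genes were drawn independently of each other, and every member of a planted list was raised equally. Camera called 5 of 5 planted lists and 0 of 45 others. In the real data, which hold correlated genes, it called at least 1 list in 7 of the 9 splits of the samples that mix the genotypes. Such a split still holds more libraries of one genotype on one side, so these calls give no rate of false calls. With an estimated correlation 0 lists passed, so a list past the threshold at the preset correlation is weak evidence. A test of gene positions along chromosomes, on 24033 ordered loci, gave a permutation p of 1.00 for 36 scattered genes and of 0.0001, the smallest that 10000 permutations can give, for 36 planted in blocks.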

Results

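Gene expression was measured in the basal 1 cm of young rice shoots, the part that holds the stem and the shoot apical meristem, 20 days after germination under 16 h days. The groups were wild-type Nipponbare and the knockout line pine1-1a, with 3 samples of 8 pooled plants in each. PINE1 encodes a C2H2 zinc finger protein that the study ties to internodes that stay short before flowering. Recovered reads came to 28699032, 32515392 and 36250239 in wild type replicates 1 to 3, and to 31997002, 30990317 and 27918842 in pine1 replicates 1 to 3. The 10 most abundant genes took between 2.56% and 2.92% of the reads of a library. The first principal component held 59.9% of the variance and separated the genotypes. Replicates of a genotype differed by more than sampling noise, with a chi-square of 6.47 to 10.3 per degree of freedom between pairs. The labels name pools of plants and no separate sowings, so p-values measure the spread between these samples.

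PINE1 (Os12g0617000, chromosome 12) was read in every library, and its RNA was higher in the libraries labelled pine1. Normalized reads were 3569, 3674 and 2943 in wild type replicates 1 to 3 and 5199, 5044 and 4173 in pine1 replicates 1 to 3. The mean was 3396 ± 395 in wild type and 4805 ± 553 in pine1 (SD, n = 3 each), a log2 fold change of 0.50 (SE 0.10, 95% interval 0.27 to 0.73, limma adjusted p = 0.021). The authors' deposited table, which describes the gene as similar to a drought and salt tolerance protein, gives -0.50 for wild type over pine1. The kind of allele is not given in the sources used here, and a small frameshift allele need not lower the RNA, so the level does not check the labels. All directions given for pine1 therefore refer to the libraries labelled pine1. The call was lost without wild type replicate 1 (adjusted p = 0.0513), without wild type replicate 3 (0.0552), without pine1 replicate 1 (0.0579) and without pine1 replicate 2 (0.0722), and against a fold of 1.5 (1.00), within a range of 2.0e-05 to 1.00 over all settings.

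Which transcripts of the basal stem and apex differ when PINE1 is knocked out was the question of the single comparison. Of 5 fixed loci of KNOX homeobox genes, which maintain undifferentiated meristem cells, 3 rose in pine1 and 2 did not pass (camera adjusted p = 0.033, and 0.33 with an estimated correlation). OSH15 (Os07g0129700) rose 2.11-fold, from 763 ± 113 to 1610 ± 236 normalized reads (SD, n = 3 each), and OSH1 (Os03g0727000) rose 2.47-fold, from 381 ± 87.3 to 931 ± 148. Of 8 fixed loci of gibberellin synthesis 3 rose and 5 did not pass (adjusted p = 0.047; adjusted p = 0.33 with an estimated correlation). OsKAO (Os06g0110000), 1 of the 3, was 3.22-fold higher; of genes matched by name, OsGA20ox7 (Os08g0560000) was 4.05-fold higher and KO4 (Os06g0569500) fell. Among flowering genes, the MADS-box gene OsMADS56 (Os10g0536100) rose 2.70-fold and Rcn4 (Os04g0411400), a relative of TERMINAL FLOWER 1, rose 4.57-fold. Laccases, which oxidise lignin precursors in the wall, rose in all 12 called members, led by OsLAC12 (Os03g0297900) at 9.12-fold. The called core histone and photosynthesis genes rose, most of them by small amounts.

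By limma, 970 genes were higher and 589 lower in pine1 among 24149 tested, so 62.2% of the 1559 calls were rises. Of these, 415 rose and 166 fell by at least 2-fold. The values of the genotypes did not overlap in 26.4% of all genes tested, where chance gives 10%. Of the 1559, 1503 are among the 1962 genes of the authors' deposited table, and 459 genes of that table were not called here. The number of calls moved with the samples: leaving out wild type replicate 1 gave 570 higher and 266 lower, leaving out wild type replicate 2 gave 272 lower, and leaving out wild type replicate 3 gave 388 lower. A filter of 5 CPM left 16674 genes and 624 higher calls, and a test against a fold of 1.5 left 174 higher and 51 lower.

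Among genes that met the rule for named genes, the largest rises were mostly in genes nearly or fully without reads in wild type. Genes without an informative name, among them Os03g0115800 below, are left out of this ranking. Os06g0271500, an En/Spm-like transposon gene, had 0 reads in wild type and 6706 ± 128 normalized reads in pine1 (SD, n = 3), at least 2306-fold higher. Os08g0340700, a non-coding transcript, went from 0 to 331 ± 18.9 (at least 114-fold), Os11g0229100 from 0 to 206 ± 10.9 (at least 70.8-fold) and Os04g0510000 from 0 to 192 ± 48.6 (at least 65.9-fold). Os11g0100200, listed as similar to ALY, an mRNA export adaptor, had 4 reads in wild type in all and 726 ± 28.8 normalized reads in pine1, a read ratio of 569 (95% counting interval 222 to 2089). Os11g0233400, known by a clone name, rose 209-fold from 18.7 ± 6.66 to 3978 ± 135 normalized reads (log2 7.71, SE 0.21). The neighbours Os07g0248800 and Os07g0248900, the latter with a MuDR transposase domain, rose by 7.35 (SE 0.80) and 7.29 (SE 0.53) on the log2 scale, both from means under 10 normalized reads. These sizes hang on few wild type reads: the former was 6.40 without wild type replicate 2, 8.42 without wild type replicate 3 and 6.56 with edgeR, and the latter 8.02 without wild type replicate 3. All 8 passed the test, with the highest adjusted p, 9.9e-04, at Os07g0248800.

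Among genes that met the same rule, the largest falls included a pair of neighbouring F-box genes, whose products choose proteins for degradation. OsFbox607 (Os11g0539600) went from 351 ± 17.9 normalized reads to 0 (at least 113-fold lower), and OsFbox608 (Os11g0539700) fell by 5.42 on the log2 scale (SE 0.38), from 158 ± 24.2 to 3.03 ± 1.97. Os11g0235700, similar to FHY1, a carrier of phytochrome A into the nucleus, fell by 3.93 (SE 0.14), from 522 ± 15.1 to 33.5 ± 4.56. By locus identifier it lies near the stretch of chromosome 11 taken up under other observations. OsZFP6 (Os02g0552700), a zinc finger gene by its symbol but a retrotransposon gene by its description in the authors' deposited table, fell 14.4-fold to 42.4 ± 22.1, and the thionin gene OsTHI3 (Os06g0513050), of a family of antimicrobial peptides, fell from 2428 ± 1039 to 255 ± 210 (log2 -3.59, adjusted p = 0.012; -2.76 without pine1 replicate 1 and -4.26 without pine1 replicate 3). The serine carboxypeptidase gene OsSCP61 (Os11g0461000) fell by 2.85 on the log2 scale, from 1149 ± 74.8 to 167 ± 63.7. Os05g0100100, known by a clone name, fell by 3.46 and OsWD40-134 (Os06g0678650) by 2.74 on the log2 scale.

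In 36 genes, a group singled out after the values were seen, every library of one genotype had at most 3 reads while the other genotype had a mean of at least 30. Of these, 30 were absent from wild type and 6 from pine1, all 36 were called, and their median level in the genotype that had them was 127 reads. Apart from those above, Os03g0115800 went from 0 to 4753 ± 388 normalized reads (at least 1635-fold higher) and Os07g0442800 from 1594 ± 138 to 0 (at least 513-fold lower). Chromosome 11 held 11 of the 36, and 8 of the 36 lay within 10 tested loci of another. Among tested loci of chromosome 11, 9.93% were called, against 5.13% to 8.13% on the other chromosomes.

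**Figure D1:**
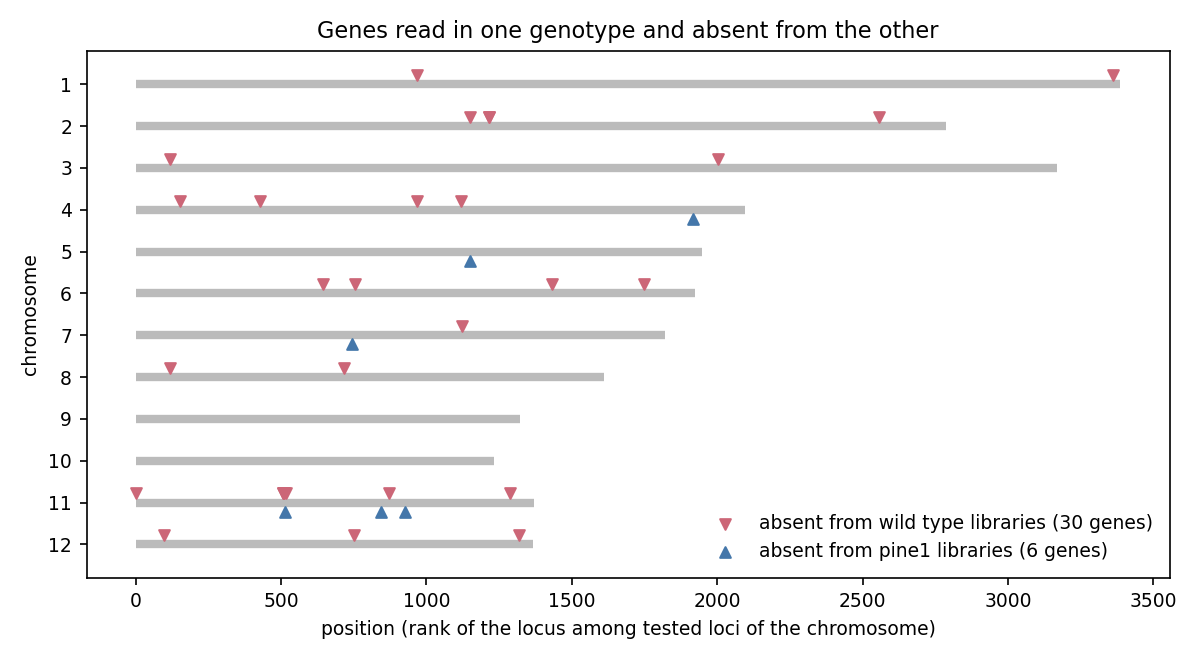
Positions of the 36 genes read in one genotype and absent from the other, by chromosome and by rank of the locus among the tested loci of that chromosome (grey bars). Triangles above a bar mark the 30 genes absent from wild type and triangles below it the 6 absent from pine1; chromosome 11 holds 11 of them.

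**Figure D2:**
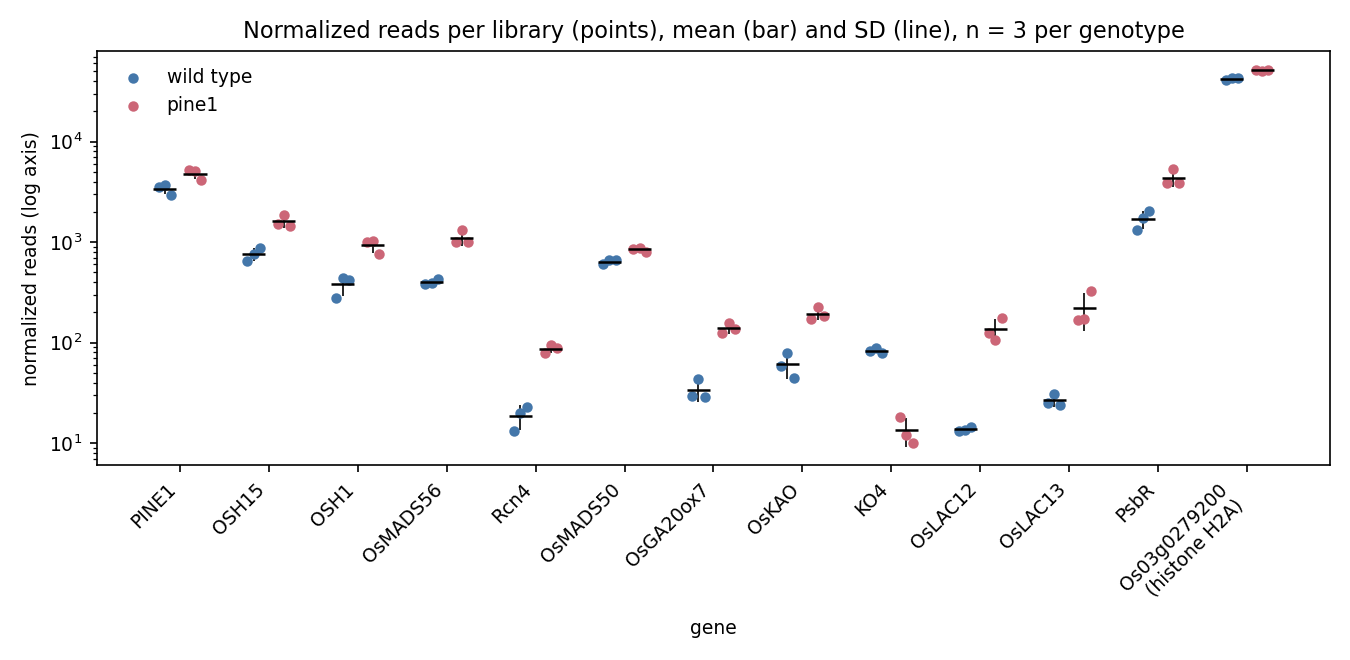
Normalized reads (log axis) of 13 genes in each library, blue for wild type and red for pine1; points are libraries, bars the mean and thin lines the SD (n = 3 per genotype). KO4 lies lower in pine1 and the other 12 genes lie higher, with no overlap between the genotypes.

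The 5 fixed loci tested in the KNOX and BELL homeobox list are all KNOX genes. Of these, 3 rose, 0 fell and 2 did not pass, and 3 rose when adjusted over the list alone. Their median log2 fold change was 0.78, and camera placed the list above other genes (adjusted p = 0.033). The list did not pass with an estimated correlation (adjusted p = 0.33 with an estimated correlation), without wild type replicate 1 (0.0576) or without pine1 replicate 2 (0.0822). With name matches, 6 homeobox genes were called and all 6 rose, by 0.78 to 1.55 on the log2 scale. OSH15, described in the authors' deposited table as acting in internode development and in repression of lignin synthesis, rose by 1.08 (SE 0.13, adjusted p = 0.0014). OSH1 rose by 1.30 (SE 0.18, adjusted p = 0.0032). The 6 rises against 0 falls did not differ from the split of the other named calls (Fisher's exact p = 0.089, adjusted 0.24).

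In the florigen and photoperiod list 12 loci were tested, of which 3 rose, 0 fell and 9 did not pass, while 4 rose and 1 fell when adjusted over the list alone. OsMADS56, a negative regulator of flowering in long days, rose from 403 ± 26.5 to 1100 ± 187 normalized reads (log2 1.43, SE 0.12, adjusted p = 1.6e-04). Rcn4 rose from 18.8 ± 5.13 to 87.5 ± 8.49 (log2 2.19, SE 0.25, adjusted p = 0.0013). OsMADS50 (Os03g0122600), a flowering activator, rose by 0.40 on the log2 scale (adjusted p = 0.013), a call lost without wild type replicate 1 (0.0583) and without pine1 replicate 2 (0.0503). Camera placed the list above other genes (adjusted p = 0.047; adjusted p = 0.33 with an estimated correlation). The called members include both an activator and a negative regulator of flowering, so the shift of the list gives no direction for flowering. The list did not pass without wild type replicate 1 (0.0742), wild type replicate 2 (0.0554), pine1 replicate 2 (0.0822) or pine1 replicate 3 (0.0890). Nor did it pass with the replicate block (camera adjusted p = 0.0548) or the filter of 5 CPM (0.0743). Of the floral meristem MADS genes 1 locus was tested and of the SVP-like MADS genes 3, and none of the 4 passed, over all genes or over the list alone.

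Circadian clock genes, which also mark the hour of harvest, stood beside the flowering genes. Of 9 clock loci tested, 0 passed over all genes and 1 rose when adjusted over the list alone, yet all 9 fold changes were above 0, with a median of 0.14. Camera gave an adjusted p of 0.033 for the list (adjusted p = 0.33 with an estimated correlation), which was lost without wild type replicate 1 (0.0742), pine1 replicate 2 (0.0822) and pine1 replicate 3 (0.0890). With the filter of 5 CPM the call was lost too (camera adjusted p = 0.0685). The loci fixed as GI, PRR37 and ELF3-1 are in both the clock list and the florigen and photoperiod list, so the results of these lists overlap. GI (Os01g0182600) had a log2 fold change of 0.45 with an adjusted p of 0.13, was 0.28 without pine1 replicate 3, and passed without pine1 replicate 1 (0.0156) and with DESeq2 (0.0137).

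Of 8 gibberellin synthesis loci tested, 3 rose, 0 fell and 5 did not pass, and 3 rose when adjusted over the list alone. They were OsKAO, an oxidase of the middle of the pathway (60.7 ± 17.2 to 194 ± 28.0 normalized reads, log2 1.69, SE 0.22, adjusted p = 0.0024), 20ox2 (Os01g0883800), the semidwarf gene of rice breeding (log2 0.59, adjusted p = 0.022), and OsCPS1 (Os02g0278700), at the entry of the pathway (log2 1.55, adjusted p = 0.027). Leaving out any of 5 of the 6 libraries ended the calls of 20ox2 (adjusted p up to 0.0818) and of OsCPS1 (up to 0.0790): all but pine1 replicate 3 for the former, and all but wild type replicate 2 for the latter. Camera placed the list above other genes (adjusted p = 0.047, and 0.33 with an estimated correlation). The call was lost without wild type replicate 1 (0.0594), wild type replicate 2 (0.0554), pine1 replicate 1 (0.112) and pine1 replicate 2 (0.117). It was also lost with the replicate block (camera adjusted p = 0.0548) and the filter of 5 CPM (0.0685). With name matches 7 genes were called, 6 higher and 1 lower (Fisher's exact p = 0.27, adjusted 0.49). Among them, OsGA20ox7 rose from 33.9 ± 8.07 to 139 ± 16.3 (log2 2.02, SE 0.21, adjusted p = 7.5e-04). The 1 that fell was KO4, an oxidase described in the authors' deposited table as part of phytoalexin synthesis, from 83.0 to 13.5 normalized reads (log2 -2.57, SE 0.26, adjusted p = 6.9e-04).

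Few genes of gibberellin inactivation and signalling were called. Of 2 inactivation loci tested, Os05g0158600, fixed beforehand as GA2ox1, rose by 0.74 on the log2 scale (adjusted p = 0.049), a call that every left-out library ended (up to 0.148), as did DESeq2 (0.0510), upper-quartile scaling (0.0510) and the lack of a filter (0.0509), and 1 rose when adjusted over the list alone. Os05g0208500, which carries a related name in the authors' deposited table, fell by 0.28 (adjusted p = 0.019; 0.0773 without wild type replicate 2 and 0.0661 without wild type replicate 3). None of 5 signalling loci passed over all genes (camera adjusted p = 0.21), and 2 rose when adjusted over the list alone. The 4 called genes, none of them a fixed locus, were matched by a receptor-like name. Whether they act in gibberellin signalling was not checked. Of these 4, 3 rose and 1 fell, among them Os11g0240600, a hydrolase-fold gene (log2 1.11, adjusted p = 6.3e-04), and OsCDAP3 (Os07g0162900, log2 0.79, adjusted p = 0.0093). Os07g0606800 fell by 0.43 (adjusted p = 0.040), a call lost when any library but pine1 replicate 2 was left out (up to 0.145). In the list of gibberellin-regulated GASA proteins 1 gene was called, and it fell.

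The called secondary wall genes, most of them matched by name, were mostly higher in pine1. Of 4 fixed loci 1 rose, 0 fell and 3 did not pass, and 2 rose when adjusted over the list alone. With name matches 19 genes were called, 18 higher and 1 lower, a split that differed from that of the other named calls (Fisher's exact p = 0.0030, adjusted 0.011), with a median log2 fold change of 1.32. That test takes the 12 called laccases among them as independent genes. OsLAC12 rose from 13.7 ± 0.74 to 136 ± 36.0 normalized reads (log2 3.19, SE 0.23, adjusted p = 9.2e-05) and OsLAC13 (Os05g0458300) from 26.6 to 221 (log2 2.94, SE 0.27, adjusted p = 3.3e-04). All 12 called laccases rose, by 0.92 to 3.19, and all 3 called phenylalanine ammonia-lyases, which open the lignin pathway, rose by 0.47 to 0.74. OsCesA4 (Os01g0750300), a cellulose synthase of the secondary wall named here after its values were seen, rose from 2504 to 4189 (log2 0.74, adjusted p = 0.0096). OsACS6 (Os01g0901600), a 4-coumarate ligase-like gene, fell by 1.08 (adjusted p = 0.026; lost without wild type replicate 1 or 2 or pine1 replicate 2 or 3, up to 0.0865). The 5 primary wall cellulose synthases did not pass over all genes, with a camera adjusted p of 0.087, and 2 fell when adjusted over the list alone. They passed downward without wild type replicate 3 (0.0324).

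Root markers were tested at 4 loci beside these genes. Os01g0704100 rose by 1.52 on the log2 scale (adjusted p = 0.032), from 6.50 ± 1.27 normalized reads, and every left-out library (up to 0.118) and DESeq2 (0.0738) ended that call. Os02g0662000, the 1 abundant locus, had a log2 fold change of -1.18 (95% interval -2.09 to -0.26, adjusted p = 0.13), which was -0.63 without pine1 replicate 1, the library with the lowest value, and -1.49 without pine1 replicate 3. Os02g0745100 had 0.69 (adjusted p = 0.070) and Os03g0107300 had 3.78 (adjusted p = 0.089), which was 5.31 without wild type replicate 2 (0.0024) and 3.02 without wild type replicate 1 or 3. Adjusted over the list alone, 3 rose and 1 fell.

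**Figure D3:**
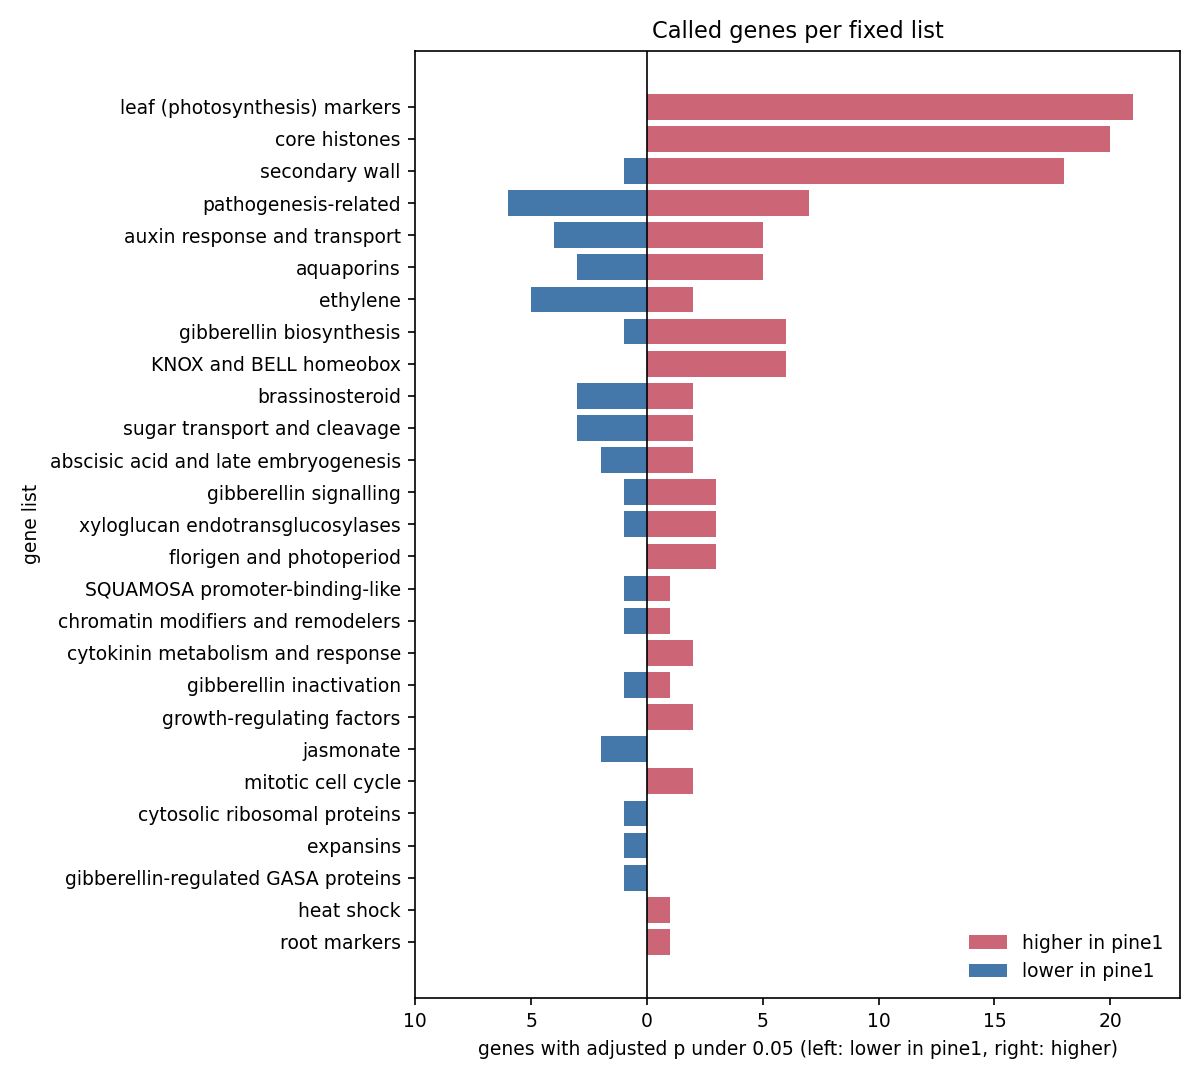
Called genes per fixed gene list, counted to the right for genes higher in pine1 and to the left for genes lower in pine1 (limma adjusted p under 0.05, fixed loci and name matches together, lists without calls left out). Leaf markers (21), core histones (20) and secondary wall genes (18) have the most rises, and ethylene (5) and pathogenesis-related genes (6) the most falls. These counts include some genes caught by name that do not do what the list says.

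The called core histone genes, all matched by name among the authors' selected genes, rose, most of them by small amounts. The list had 20 called genes, all 20 higher (Fisher's exact p = 8.9e-05, adjusted 4.9e-04), but the names also caught the homeobox gene OSH3 and the transcription factor subunit OSHAP5C. Without these and Os01g0974600, the remaining 17 rose by 0.19 to 0.33 on the log2 scale, with a median of 0.26 (Fisher's exact p = 5.1e-04, adjusted 0.0056 over 11 name groups chosen after the values were seen). Os03g0279200, an H2A gene, rose 1.21-fold from 42181 ± 868 to 51218 ± 667 (log2 0.28, SE 0.04, adjusted p = 0.0040). Os01g0974600, also listed as H2A, had 1 read in wild type in all and 159 ± 18.8 normalized reads in pine1, a read ratio of 499 (95% counting interval 89.2 to 19763). Of 4 mitotic loci tested 1 rose, over all genes and over the list alone, and with name matches 2 rose: CDKB2 (Os08g0512600) by 0.20 (adjusted p = 0.030) and CycB1 (Os01g0805600) by 0.22 (0.047). Every left-out library ended the call of CDKB2 (up to 0.122). That of CycB1 was ended by any but wild type replicate 1 (up to 0.162), by upper-quartile scaling (0.0513) and by the replicate block (0.0567). The name patterns for DNA replication genes and tubulins, which reach only genes in the authors' deposited table, matched no called gene.

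All 21 called leaf markers, photosynthesis genes matched by name only, were higher in the libraries where the called histone and wall genes were higher (Fisher's exact p = 5.2e-05, adjusted 4.9e-04). They rose by 0.24 to 1.35 on the log2 scale with a median of 0.35. PsbR (Os07g0147500), of photosystem II, rose from 1704 ± 353 to 4325 ± 822 normalized reads (log2 1.35, adjusted p = 0.0016), and Lhcb1.1 (Os01g0720500), of the light-harvesting antenna, from 2426 ± 497 to 5368 ± 1006 (log2 1.15, adjusted p = 0.0035). The 26 organelle-encoded genes, of which 16 had a fold change below 0, did not pass, over all genes or over the list alone (camera adjusted p = 0.20). The list passed downward without wild type replicate 3 (0.0365).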

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

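The alternatives were fixed beforehand, except that edgeR on the recovered reads, TMM scaling and some settings for PINE1 and the named genes were chosen after the data were examined. The counts of 970 higher and 589 lower genes stayed within 1.5 times under other scalings, DESeq2, limma-voom, edgeR, no filter and both pseudocounts, at 925 to 1177 higher and 579 to 799 lower. The filter of 5 CPM gave 624 higher among fewer genes tested, and the test against a fold of 1.5, which asks for larger changes, gave 174 higher and 51 lower. Leaving out 1 library gave 570 to 760 higher and 266 to 550 lower, with fewer samples in each fit. PINE1 kept its direction in every setting, with log2 fold changes of 0.40 to 0.60; against a fold of 1.5 its value of 0.50 did not pass (adjusted p = 1.00), and without 1 library it was 0.40 to 0.60 and passed only without wild type replicate 2 (0.0311) or pine1 replicate 3 (0.0135).

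Gene lists depended most on the setting. Of the 4 lists that passed with camera, 0 passed with an estimated correlation and 0 with the filter of 5 CPM, under which the KNOX and BELL list had too few members to test; fry called 2, the florigen and gibberellin signalling lists, and leaving out 1 library gave 0 to 6. The stricter filter and the left-out libraries leave fewer genes or samples; for the estimated correlation and fry the cause was not tested.

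Whether the replicate numbers pair the samples was not settled. Same-numbered libraries deviated from their group means with correlations across genes of 0.0551, 0.0225 and 0.134, and differently numbered ones with -0.241 to 0.161. Not every sample correlated best with its own number, yet the block gave more calls. With the replicate block 1195 genes were higher and 799 lower, 2 lists passed (KNOX and BELL, adjusted p = 0.030, and clock, 0.0025) while the florigen and gibberellin biosynthesis lists did not (both 0.0548), PINE1 had a log2 fold change of 0.50 (adjusted p = 6.7e-04), and among the called named genes only CycB1 did not pass (0.0567). GI (0.0274), Os02g0662000 (0.0186) and Os03g0107300 (0.0126), not called without the block, passed with it.

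Of 60 called genes named in the text with values of their own, besides PINE1, 57 passed with each of TMM, median-of-ratios and upper-quartile scaling, DESeq2, edgeR, no filter and the replicate block, 45 passed whichever library was left out, and 0 reversed. Of 6 more called genes, named without values, 6 passed with each of the former, 5 passed whichever library was left out, and 0 reversed. None of these genes was followed under limma-voom, the filter of 5 CPM, the other pseudocounts or the test against a fold of 1.5. Genes near the threshold were lost in fits without 1 library, which have fewer samples. Simulated changes of 1.5-fold were recovered in 51.5% of genes (at most 66.2% in 6 further draws), so smaller changes can be missed at this depth and number of samples. Sparse genes were not among those changed in the simulation, so these shares do not cover them.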

Other observations

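In this part, the tests of gene positions, of transposon names, of root markers and of scaling, the comparison of signs and the split of the samples over genes were chosen only after the results were seen; the split over gene lists was chosen before. Water channels and wall-loosening enzymes differed between the genotypes in both directions. Of 8 called aquaporins 5 were higher and 3 lower in pine1, although 1 of the 8 was caught by its name alone. OsPIP2 (Os03g0861300), a water channel of the plasma membrane, rose from 13.1 ± 4.07 to 207 ± 47.8 normalized reads (SD, n = 3 each), 14.9-fold, with a limma adjusted p of 6.9e-05. OsTIP4 (Os01g0232000), of the vacuole membrane, rose by 1.37 on the log2 scale and OsTIP1 (Os03g0146100) fell by 0.46. Of 4 called xyloglucan endotransglucosylases, which rejoin wall polymers, 3 rose, led by OsXTH19 (Os03g0108300, log2 1.40, adjusted p = 0.0039), and OsXTH2 (Os11g0539200) fell by 0.45, a call lost without wild type replicate 2 or 3 or pine1 replicate 2 or 3 (adjusted p up to 0.0841). The 1 called expansin, OsEXPA21 (Os03g0377100), fell 2.83-fold (adjusted p = 0.027; lost when any library but pine1 replicate 2 was left out, up to 0.119). Both called growth-regulating factors rose: GRF3 (Os04g0600900) by 0.51, lost without wild type replicate 1 or 2 or pine1 replicate 2 or 3 (up to 0.127), and OsGRF7 (Os12g0484900) by 0.36, lost without wild type replicate 2 (0.0557).

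Hormone, defence and sugar genes were mixed as well. Of 7 called genes in the ethylene list 2 rose and 5 fell. The falls include OsACS6, the 4-coumarate ligase-like gene of the secondary wall list, which was caught by its symbol. Of the others, the ACC oxidase gene ACO7 (Os01g0580500) fell from 649 to 236 normalized reads. ACO3 (Os02g0771600), also an ACC oxidase gene, rose from 733 to 1528. Both called cytokinin genes rose, LOGL3 (Os03g0109300) by 0.73 and LOG1 (Os01g0588900) by 0.54, the latter lost without wild type replicate 1 (adjusted p = 0.0534). In the auxin list 5 rose and 4 fell, with the carrier genes OsLAX3 (Os05g0447200) higher by 1.67 and OsPILS7a (Os09g0554300) lower (log2 -0.67). Of 13 called pathogenesis-related genes 7 rose and 6 fell, with OsBetvI (Os08g0374000) rising from 196 to 635 and the germin-like gene GER8 (Os01g0952000) falling from 2839 to 974. Brassinosteroid and sugar genes each had 2 rises and 3 falls, abscisic acid genes 2 and 2, squamosa promoter-binding-like and chromatin genes 1 and 1, jasmonate genes 0 and 2, heat shock genes 1 and 0, and cytosolic ribosomal proteins 0 and 1. Names exist for the authors' selected genes only, so none of these counts is an enrichment.

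The 36 genes read in one genotype and absent from the other were more clustered than chance gives: 8 lay within 10 loci of another, against a mean of 2.04 in 10000 permutations within chromosomes (one-sided permutation p = 0.0067; 0.0788 within 20 loci, where there were still 8). Of these, 6 lie between Os11g0227300 and Os11g0234001 and are absent in both directions. A strain or donor variant between the lines is therefore a candidate explanation for this stretch and for the pair Os02g0517333 and Os02g0517421. Of the 6, only Os11g0233201 was absent from pine1. The others, like the pair, were read in pine1 and had 0 reads in wild type, so sequence missing from pine1 cannot explain them. A few variant segments leave the scattered others unexplained. By locus identifier, Os11g0233400 lies inside the stretch, Os11g0235700 just past it, and OsXTH2 (Os11g0539200) near OsFbox607 (Os11g0539600). For these genes a variant between the lines and a response to the loss of PINE1 cannot be told apart. Lost silencing of transposons was not decided, since 2 of 36 (5.56%) have a transposon name against 46 of 1467 (3.14%) other named calls (Fisher's exact p = 0.32). Loss of PINE1 and a possible history of the line in tissue culture stay open and were not tested.

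Higher RNA of the called laccase and secondary wall genes may come from more root tissue in the pine1 segments. The 1 abundant root locus, Os02g0662000, had an upper 95% bound of -0.26 against a median rise of 1.32 in the called wall genes, but it was not called (adjusted p = 0.13), and its log2 fold change of -1.18 was -0.63 without pine1 replicate 1. The 3 sparser root loci had fold changes above 0. With 1 abundant locus, root tissue and a change within the stem cannot be told apart. The rise of the called leaf markers in the same libraries leaves a different cut of the segment open, and more vascular tissue in a stem that elongates is a biological explanation that was not tested.

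PINE1 RNA was higher in the libraries labelled pine1, and 6.20% of the tested genes had a fold change at least as high. An error of library scaling may add to so small a change, although TMM and upper-quartile scaling gave 0.50 and 0.49. Exchanged labels stay open too: 1961 signs match between the tables, yet both carry the same labels and the allele was not read here. A knocked-out protein that normally lowers its own transcript is a biological explanation that was not tested.

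The 6 samples can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1559 genes and the highest of the others 0, so only the real split itself, 1 of the 10, had that many genes. For the lists the real split called 4 and the highest of the others 3, so again only the real split, 1 of the 10, had that many. Of the 9 splits that mix the genotypes, 7 called at least 1 list and 0 called a gene. Each of these splits still holds more libraries of one genotype on one side, so a list shifted between the genotypes can pass there. The genotype difference also widens the spread within each side, which makes gene calls unlikely. These splits therefore give no rate of false calls for lists or genes.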
